A study of Mus musculus with 36 samples.

How the data were processed

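Polyadenylated RNA of mouse cells was sequenced in 36 libraries, which the labels place in 18 groups of 2. MEFs from embryonic day 13.5 carried the doxycycline-inducible factors. Feeder MEFs, irradiated, lay under the ESCs and the reprogramming cells, and the counts cannot separate their RNA. RNA was extracted with TRIzol, cleaned on columns and treated with DNase, and libraries were made from 1 µg with a TruSeq kit. The timecourse and sort libraries were paired-end and received 20 ng of human 293T RNA per the labels. The remaining libraries were not described as paired-end or spiked. Groups were taken from the sample titles. For replicate 2 of the MEFs with the Cdh1 virus, the source field named day 2 reprogramming cells while title and treatment named uninduced MEFs. It was kept with the MEFs, in which Pou5f1 stood at 0.774 CPM and Cdh1 at 179 CPM.

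The deposited files held 1 table per library with 20325 mouse genes. Per the submitters' processing notes, the authors used Trimmomatic, Bowtie (versions not given) and RSEM 1.2.4 with the builds mm9 and hg18, and how these were combined was not stated. Before deposit, RSEM had estimated each gene's expected count, dividing reads that map to several genes by its model. The deposited expected counts were not normalized. The deposited TPM values were scaled by RSEM for effective gene length to a fixed sum of transcripts within each library, according to the column names and the sums of the values. The deposited FPKM column was not used. Effective length was shorter than gene length by between 59.9 and 88.8 bases in the timecourse and between 72.3 and 87.8 in the sort, and by 0 in the other libraries. TPM was therefore compared only within experiments processed alike. No human gene was in the files, so the planned scaling to the spiked RNA could not be made, and changes are relative to the other genes of a library. The genome build of the notes was not at hand, so no gene coordinate was used, and 19976 gene names matched exactly 1 current symbol.

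Expected counts were rounded to whole numbers and tested with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3 (robust dispersion and quasi-likelihood fits). Library sizes were scaled by TMM, and genes were kept by filterByExpr (minimum count 10, minimum total 15). Each fit had 1 coefficient per group. The timecourse fit held 14 libraries and tested 14473 genes, with 5852 filtered out. The sort fit held 8 libraries and tested 13968 genes, with 6357 filtered out. The lentivirus and ESC libraries, 14 together, were fitted as 1 set with 15044 genes tested and 5281 filtered out. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and all p-values of single genes come from these models fitted across all genes, with residual degrees of freedom of 7, 4 and 7 and information shared between genes. The 19 comparisons comprised differences of 2 groups and differences between effects, each tested as a contrast. CPM used the TMM library sizes.

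The 28 gene lists held 444 genes, of which 440 matched a gene of the files. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with the correlation estimated and with fry, adjusting over the lists within a comparison. Counts per list are given as adjusted over all genes and as adjusted over the list alone. ESC and MEF sets were taken at 4-fold or more from the ESC comparison. Named genes were the 6 largest increases and 6 largest decreases (4 and 4 outside the comparisons of inhibitor with control) among called genes with a mean log2 CPM of at least 3 and no overlap between the libraries of 2 groups. To these were added up to 4 members per list with the smallest p, and always Cdh1, Dot1l, Pou5f1, Sox2, Klf4 and Myc. Some genes that this rule names are not reported here. Groups, tests, lists, this rule and the alternatives of the last paragraph were fixed before the data were examined. The joint fit of the timecourse and lentivirus libraries (28 libraries, 15452 genes) was added afterwards, as were the ESC-specific genes (at least 30 CPM in ESCs and at most 0.1 CPM in MEFs) and a list of 27 imprinted genes. Sc4mol, Emr1, Tcfap2c, Tcfcp2l1, Ctgf and Cyr61 are older gene symbols, printed as in the files.

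Expected counts summed to between 18.5 M and 50.9 M per library. On simulated data with the depth and spread of the timecourse day 2 comparison, edgeR recovered 64% of 50 genes changed 1.2-fold (genes with mean counts above 50) and 98% of those changed 1.5-fold, and 14 of 13615 tested genes were false calls. For the sort the shares were 74% and 96% with 16 false calls, and for the lentivirus cells 32% and 86% with 7. Of 200 random gene sets in each, camera called 0 at an unadjusted p under 0.05, also with an estimated correlation. This does not bound false calls of lists whose genes vary together. The libraries of each group differed by more than counting noise, so no library was a copy of its partner.

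Alternatives were DESeq2 1.42.0, limma on log2 of TPM plus 1 (genes at 1 TPM or more in 2 or more libraries), RLE scaling, no low-count filter, a fit of only the compared groups, replicate number as an added factor, a 2-fold minimum, and leaving out each library. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Transcript isoforms were not analysed.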

Results

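RNA sequencing profiled mouse embryonic fibroblasts (MEFs) on the way to induced pluripotent stem cells, with and without SGC0946, a chemical inhibitor of the histone methyltransferase DOT1L. The MEFs came from mid-gestation embryos and carried doxycycline-inducible Oct4 (gene symbol Pou5f1), Klf4, Sox2 and c-Myc at the Col1a1 locus, with the transactivator at Rosa26. The series held 36 libraries in 18 groups of 2. The timecourse had 14 libraries of uninduced MEFs, day 2 cells with or without inhibitor, and day 4 cells. The day 4 cells were grown without it, or with it on days 0 to 2 (the early window), on days 2 to 4 (the mid window) or on days 0 to 4 (the full window). The sort experiment had 8 libraries of cells that were separated by surface CDH1 (E-cadherin) after 3.5 days of doxycycline and kept on doxycycline with inhibitor or vehicle until day 5.5. The lentivirus experiment had 12 libraries of MEFs carrying an empty or a Cdh1-expressing lentivirus and of day 2 cells with each virus, with or without inhibitor. Embryonic stem cells (ESCs), harvested 24 h after removal of feeder cells, gave 2 more libraries. Expected counts per library summed to between 32.9 M and 50.9 M in the timecourse and 34.9 M and 43.1 M in the sort. The lentivirus libraries held between 18.5 M and 35.9 M and the ESC libraries 30.7 M and 35.2 M.

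Levels are counts scaled to library size (CPM), given as mean ± SD of the 2 libraries of a group, and log2 fold changes are given ± SE with adjusted p-values of the edgeR quasi-likelihood test. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The coefficient of variation between replicates beyond counting noise was 3% in the timecourse, 2.3% in the sort and 5.6% in the lentivirus and ESC libraries, so small changes passed the test less readily in the last of these. Counts of Pou5f1, Sox2, Klf4 and Myc cannot separate the inducible cassette from the endogenous genes, and those of Cdh1 in the lentivirus experiment cannot separate virus from cell. The change given for a list of genes is the median over its members.

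Reprogramming without inhibitor was compared with uninduced MEFs first. Pou5f1 rose from 1.4 ± 0.218 CPM in MEFs to 210 ± 2.19 CPM at day 2. Sox2 rose by 6.06 ± 0.07 on the log2 scale (adjusted p = 6.45e-42), Myc by 1.80 ± 0.04 and Klf4, already at 153 CPM in MEFs, by 1.02 ± 0.04. Fibroblast and muscle genes fell: the matrix gene Postn went from 1230 ± 16.9 to 32.7 ± 0.166 CPM, Col1a1 from 8860 ± 134 to 1430 ± 33.8 CPM. Smooth muscle actin Acta2 went from 6360 ± 170 to 1710 ± 27.8 CPM, and Lrrc15 changed by -5.84 ± 0.07 log2. Aldh3a1, an aldehyde dehydrogenase, rose from 0.378 ± 0.0693 to 187 ± 1.5 CPM, and the sialomucin gene Podxl and the pluripotency-associated L1td1 rose by 5.97 ± 0.07 and 9.16 ± 0.10 log2. Cdh1 rose from 0.0661 ± 0.0576 CPM in MEFs to 3.03 ± 0.154 CPM at day 2 and 7.78 ± 0.348 CPM at day 4. In all, 10772 of 14473 genes changed by day 2 (5845 higher, 4927 lower) and 11893 by day 4 (5956 higher, 5937 lower).

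Lists of related genes moved together over these control days. Of 24 fibroblast matrix and identity genes, 22 fell at day 2 and 22 at day 4 (22 each adjusted over the list alone), and the list tests with camera gave adjusted p = 3.6e-45 and 3.13e-22. Mesenchymal regulators fell in 19 and 18 of 20 genes, and contractile and YAP target genes fell in 11 of 11 at both days (the same numbers adjusted over the list alone). Among them were Tagln at -1.74 ± 0.03 log2 at day 2 and Ctgf at -2.46 ± 0.03 log2 at day 4. All 17 sterol synthesis genes fell at day 2 and 16 at day 4 (also adjusted over the list alone). Fdps, which makes farnesyl diphosphate, went from 333 ± 0.204 to 66.3 ± 0.0812 CPM by day 2, and Insig1 changed by -2.62 ± 0.04 log2. All 11 skeletal and cardiac muscle genes fell at both days (11 adjusted over the list alone), with Myh3 at -7.39 ± 0.28 and Acta1 at -4.48 ± 0.12 log2 by day 2. Macrophage and leukocyte genes fell in 10 of 11 at day 2 (10 adjusted over the list alone; adjusted p = 4.21e-07), Lyz2 from 143 ± 1.23 to 14.4 ± 1.12 CPM. At day 4 that list was not called (adjusted p = 0.461), and Mrc1 rose by 1.70 ± 0.06 log2. Immediate early and heat shock genes fell in 12 of 13 at both days, Fosb by -6.05 ± 0.08 log2 at day 2. Amino acid stress and unfolded protein genes fell in 10 of 14 at day 2 and 13 at day 4 (the same numbers of both lists adjusted over the list alone). The day 2 call of the last list had adjusted p = 0.0534 with an estimated correlation. Hspa5 stood at -1.69 ± 0.03 and Mthfd2 at -2.83 ± 0.05 log2 at day 4.

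Of the DNA replication and S phase genes, 15 of 16 rose at day 2 (15 adjusted over the list alone), Mcm7 by 1.12 ± 0.03 log2. At day 4 that list was not called (adjusted p = 0.0648), with 12 genes lower and 4 higher than in MEFs (12 and 4 adjusted over the list alone). Of the G2 and M phase genes 17 of 17 rose at day 2 (17 adjusted over the list alone). At day 4, 14 of those 17 G2 and M phase genes were below MEFs and 1 above (14 and 1 adjusted over the list alone; adjusted p = 0.0114, and adjusted p = 0.11 with an estimated correlation). Pluripotency genes rose in 9 of 17 and fell in 4 at day 2, and rose in 11 and fell in 3 at day 4 (the same adjusted over the list alone; adjusted p = 0.0044 and 0.00531, and adjusted p = 0.0768 and 0.11 with an estimated correlation). Chromatin modifiers of pluripotent cells rose in 14 of 15 at day 2 (14 adjusted over the list alone; adjusted p = 0.00067, and adjusted p = 0.0547 with an estimated correlation). The methylcytosine dioxygenase Tet2 rose by 2.54 ± 0.06 log2 by day 4. Of the p53 targets and cell cycle inhibitors, 10 of 13 rose at day 4 (10 adjusted over the list alone; adjusted p = 0.0428, and adjusted p = 0.11 with an estimated correlation), with Bbc3 at 1.75 ± 0.05 log2. Of 14 inflammatory and secreted factors, 5 rose and 8 fell at day 2 (5 and 8 adjusted over the list alone; adjusted p = 0.00162 for a lower list). Their median was -0.42 and their mean 0.17, so the signs differed. TGF-beta targets fell in 9 of 10 at day 4 (9 adjusted over the list alone; adjusted p = 1.93e-06). The epithelial list was not called at either day (adjusted p = 0.949 and 0.142). Nonetheless 9 and 18 of its 24 genes rose and 6 and 3 fell (8, 18, 6 and 3 adjusted over the list alone), Spint2 by 2.44 ± 0.08 log2 at day 4.

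The inhibitor was then compared with its absence at day 2. Epithelial genes were higher with the inhibitor. Cdh1 rose from 3.03 ± 0.154 to 7.39 ± 0.371 CPM, a log2 change of 1.29 ± 0.11 (adjusted p = 2.07e-11), keratin Krt8 by 1.26 ± 0.14 and the protease inhibitor gene Spint2 by 0.74 ± 0.10. The inducible factors were lower, by about the same amount each. Pou5f1 fell from 210 ± 2.19 to 175 ± 0.828 CPM (log2 change -0.26 ± 0.04), Sox2 by -0.24 ± 0.04, Klf4 by -0.25 ± 0.04 and Myc by -0.19 ± 0.03. Dot1l itself, the gene of the inhibited enzyme, was at 87.7 ± 3.13 CPM without and 89.9 ± 2.45 CPM with the inhibitor (adjusted p = 0.618). Among the genes with large increases were the integrin gene Itga3 (1.03 ± 0.08), and the ketone body enzyme gene Bdh1 (0.98 ± 0.10). Others were the guidance cue gene Ntn1 (0.95 ± 0.06), the lipid-transfer gene Esyt3 (0.90 ± 0.09) and the Notch ligand gene Jag2 (0.83 ± 0.08). Among the genes with large decreases were the imprinted gene Nnat (-1.19 ± 0.07), the transcription factor gene Nfix (-0.62 ± 0.04), Ggh (-0.61 ± 0.05) and the Wnt receptor gene Fzd5 (-0.60 ± 0.05). In all 2583 of 14473 genes changed, 1264 higher and 1319 lower, and 214 of the higher but 9 of the lower ones by 2-fold or more.

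The epithelial list rose at day 2 in 11 of 24 genes, with 1 lower (12 and 1 adjusted over the list alone; camera adjusted p = 4.23e-10). Trophoblast-associated genes rose in 4 of 7 and epidermal genes in 3 of 9 (6 and 5 adjusted over the list alone; adjusted p = 0.00179 and 0.00216, the latter adjusted p = 0.0644 with an estimated correlation). Fibroblast matrix genes rose in 11 of 24, with 1 lower (13 and 1 adjusted over the list alone; adjusted p = 0.000187). The collagen cross-linking enzyme gene Lox rose from 505 ± 4.41 to 649 ± 6.71 CPM and Col5a1 by 0.26 ± 0.03 log2. The contractile and YAP target list was lower in 6 of 11 genes and higher in 1 (6 and 2 adjusted over the list alone; adjusted p = 0.000494, and adjusted p = 0.163 with an estimated correlation). Cnn1, Actg2, Myl9 and Tagln, all encoding contractile proteins, changed by -0.56, -0.34, -0.32 and -0.30 log2, whereas the YAP target gene Cyr61 changed by 0.36 ± 0.03. TGF-beta targets rose in 6 of 10 and fell in 1 (6 and 1 adjusted over the list alone; adjusted p = 4.51e-05), with Id1 at 0.44 ± 0.06. Secreted inflammatory factors rose in 5 of 14 and fell in 1 (6 and 1 adjusted over the list alone; adjusted p = 1.6e-05), with the chemokine genes Ccl2 at 0.60 ± 0.04 and Cxcl1 at 0.55 ± 0.07. All 4 reprogramming factors fell (4 adjusted over the list alone; adjusted p = 2.06e-06).

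Further lists were called with the inhibitor at day 2. Sterol synthesis genes fell in 8 of 17 (8 adjusted over the list alone; adjusted p = 0.000144), Dhcr7 by -0.31 ± 0.06 and Fdft1 by -0.23 ± 0.04 log2. S phase genes fell in 7 of 16 (8 adjusted over the list alone; adjusted p = 1.6e-05), Mcm6 and Rrm1 by -0.25 ± 0.03 each. Hox, Meis and Pbx genes fell in 10 of 38 and rose in 2 (13 and 2 adjusted over the list alone; adjusted p = 0.000378), with Hoxa10 at -0.49 ± 0.07 and Hoxc6 at -0.46 ± 0.08. Interferon response genes fell in 5 of 14 and rose in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.03, and adjusted p = 0.122 with an estimated correlation), Isg15 from 25.3 ± 1.02 to 19.7 ± 0.352 CPM. DOT1L partners and elongation factors fell in 2 of 13 and chromatin modifiers in 4 of 15 (2 and 4 adjusted over the list alone; adjusted p = 0.0492 and 0.0447, and adjusted p = 0.122 and 0.208 with an estimated correlation). Neural genes rose in 5 of 12 and fell in 1 (5 and 1 adjusted over the list alone; adjusted p = 0.00783, and adjusted p = 0.0547 with an estimated correlation), Tubb3 by 0.57 ± 0.06 log2. Leaving out any library lowered the count of 2583. It was lowered to 1581 and 1577 without day 2 control replicate 1 or 2, and to 1583 and 1510 without inhibitor replicate 1 or 2. On the deposited TPM values, limma called 1205 genes higher and 501 lower.

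By day 4 the full window of inhibitor had changed more genes, 5036 of 14473 (2752 higher, 2284 lower; 741 and 51 of them by 2-fold or more), or 2503 higher and 3005 lower without the low-count filter. Cdh1 rose from 7.78 ± 0.348 to 27.9 ± 1.28 CPM (log2 change 1.84 ± 0.08, adjusted p = 5.23e-21), Krt8 from 3.59 ± 0.23 to 16.5 ± 0.67 CPM. The desmosome gene Dsp rose from 36.7 ± 1.93 to 79.3 ± 0.695 CPM. The pluripotency regulators Nanog and Sall4 rose from 0.713 ± 0.151 to 3.39 ± 0.393 CPM and from 0.244 ± 0.0816 to 2.65 ± 0.491 CPM. The growth factor gene Igf2 went from 569 ± 6.8 to 255 ± 3.39 CPM, the IGF-binding protein gene Igfbp5 from 68.7 ± 0.395 to 17.3 ± 0.449 CPM, and the chemokine gene Cxcl12 from 232 ± 1.37 to 118 ± 2.59 CPM. Further genes with large increases were Spint1 (1.87 ± 0.09), the ciliogenesis regulator Foxj1 (1.82 ± 0.10), Col28a1 (1.59 ± 0.09) and Gprc5c (1.58 ± 0.10). Further large decreases were Abi3bp (-1.49 ± 0.07), the CXCL12 receptor gene Cxcr4 (-1.41 ± 0.09), Hic1 (-1.30 ± 0.09) and Meox2 (-1.17 ± 0.07). Dot1l was slightly higher, at 92.1 ± 4.71 against 77.3 ± 0.315 CPM (0.25 ± 0.04, adjusted p = 2.93e-06). Pou5f1, Sox2, Klf4 and Myc were lower by -0.32, -0.30, -0.27 and -0.33 log2 (4 of 4 also adjusted over the list alone; adjusted p = 0.000138, and adjusted p = 0.0872 with an estimated correlation).

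Of the epithelial list, 20 of 24 genes rose and none fell at day 4 (21 and 0 adjusted over the list alone), with a median of 1.85 log2 and camera adjusted p = 6.99e-31. TGF-beta targets rose in 7 of 10 and fell in 2 (7 and 2 adjusted over the list alone; adjusted p = 1.81e-08), Tgfbi by 0.41 ± 0.03 log2. Hox, Meis and Pbx genes fell in 26 of 38 and rose in 2 (26 and 3 adjusted over the list alone; adjusted p = 2.66e-08), Hoxc6 by -0.86 ± 0.07, Hoxa11 by -0.82 ± 0.07 and Hoxc8 by -0.65 ± 0.06. The p53 targets and cell cycle inhibitors fell in 9 of 13 and rose in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.000138), Cdkn1c by -0.64 ± 0.04. Trophoblast-associated genes rose in 6 of 7 (6 adjusted over the list alone; adjusted p = 0.00175, and adjusted p = 0.0543 with an estimated correlation), among them Tcfap2c, a transcription factor gene of trophoblast and germ cells, at 2.22 ± 0.16. Glycolysis genes rose in 10 of 12 and immediate early and heat shock genes in 8 of 13 (10 and 9 adjusted over the list alone; adjusted p = 0.00192 and 0.00294, and adjusted p = 0.222 and 0.25 with an estimated correlation).

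Mesenchymal genes were mixed at day 4. The mesenchymal regulators rose in 11 of 20 and fell in 4 (11 and 4 adjusted over the list alone; adjusted p = 0.0243), with Tgfb1 at 0.91 ± 0.06 and Twist2 at -1.02 ± 0.08 log2. The fibroblast list rose in 16 of 24 and fell in 6 (16 and 6 adjusted over the list alone; adjusted p = 0.00639). Both calls were lost with an estimated correlation (adjusted p = 0.0872 for each). The contractile and YAP target list, lower at day 2, was called higher (6 higher and 3 lower of 11, also adjusted over the list alone; adjusted p = 0.0178, and adjusted p = 0.366 with an estimated correlation). The YAP target genes Ctgf and Cyr61 rose by 0.71 ± 0.03 and 0.67 ± 0.03, while Tagln and Actg2 stayed lower by -0.22 ± 0.03 and -0.28 ± 0.04. The pluripotency list was not called (9 higher and 5 lower of 17, and 10 and 5 adjusted over the list alone; adjusted p = 0.0636), with Tcfcp2l1 at 0.88 ± 0.09. Nor were the interferon response list (adjusted p = 0.267), although Gbp2 rose by 1.61 ± 0.13, and the inflammatory list (adjusted p = 0.663), although Ccl2 rose by 0.72 ± 0.05. The plot of lists by comparison shows these medians.

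**Figure D1:**
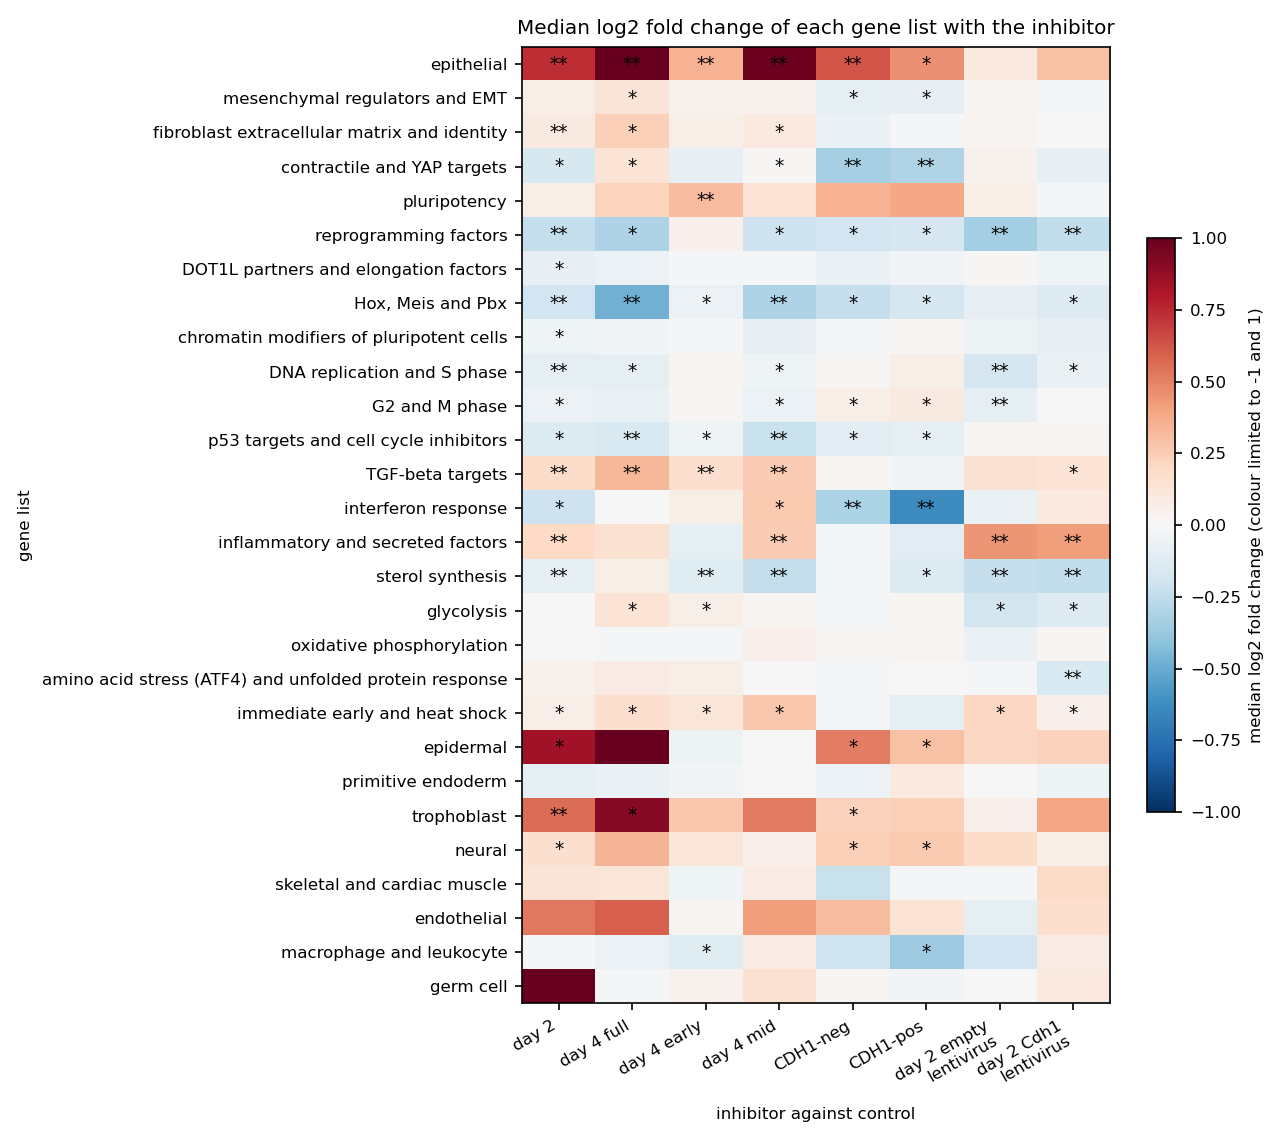
Median log2 fold change of each of 28 gene lists (vertical axis) in the 8 comparisons of inhibitor with control (horizontal axis), as colours with the scale beside them, with 1 star for lists called by camera and 2 for those also called with an estimated correlation. The epithelial list reached a median of 1.85 in the full window at day 4.

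The windows asked when the inhibitor had to be present for the day 4 changes. After the early window, with the inhibitor withdrawn for days 2 to 4, 815 genes differed from the day 4 control (461 higher, 354 lower). Cdh1 was at 12.2 ± 0.495 against 7.78 ± 0.348 CPM (0.65 ± 0.09 log2, adjusted p = 1.74e-06). The tight junction gene Cldn3 stood at 0.91 ± 0.12 and the junction adhesion gene F11r at 0.55 ± 0.06. Bex4 and Bex1 rose by 0.95 ± 0.08 and 0.81 ± 0.07, Afap1l1 by 0.71 ± 0.06, Sall4 by 2.41 ± 0.37 and L1td1 from 98 ± 2.43 to 127 ± 2.83 CPM. Abi3bp and Meox2 fell by -0.52 ± 0.06 and -0.48 ± 0.06. The reprogramming factors were not called (Pou5f1 0.03 ± 0.04, Sox2 0.08 ± 0.04, Klf4 0.09 ± 0.04, Myc 0.01 ± 0.03, smallest adjusted p = 0.176), nor was Dot1l (0.07 ± 0.04). The epithelial list rose in 7 of 24 genes and the pluripotency list in 6 of 17 (9 and 6 adjusted over the list alone, with 1 lower in each; both camera adjusted p = 2.73e-07). TGF-beta targets rose in 4 of 10 (6 adjusted over the list alone; adjusted p = 3.69e-10). Sterol synthesis genes fell in 7 of 17 (13 adjusted over the list alone; adjusted p = 2.25e-11), Fdps by -0.26 ± 0.03. Immediate early and heat shock genes rose in 4 of 13 and macrophage genes fell in 2 of 11 (7 and 2 adjusted over the list alone; adjusted p = 5.7e-06 and 0.00151, and adjusted p = 0.125 and 0.116 with an estimated correlation). Dusp1 stood at 0.40 ± 0.06 and Lyz2 at -0.42 ± 0.04. The count of 815 was 400 and 380 without day 4 control replicate 1 or 2, 415 and 450 without early window replicate 1 or 2, 1544 when only these 2 groups were fitted, and 490 on TPM values.

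The mid window, with the inhibitor present on days 2 to 4 only, changed 3968 genes (2020 higher, 1948 lower). Cdh1 rose to 21 ± 1.43 CPM (1.44 ± 0.09 log2, adjusted p = 1.74e-16), Krt8 by 1.25 ± 0.11 and Cldn3 by 1.58 ± 0.12. The protease gene Pappa2 rose by 1.87 ± 0.10 and the receptor tyrosine kinase gene Ret from 13.6 ± 0.409 to 34.6 ± 0.119 CPM. Nfix fell from 106 ± 0.692 to 62.7 ± 0.224 CPM, Igfbp5 by -0.78 ± 0.04, Bcat1 by -0.74 ± 0.04, Hic1 by -0.83 ± 0.08 and Fgf4 by -0.78 ± 0.09. Each factor was lower, Pou5f1, Sox2, Klf4 and Myc by -0.27, -0.21, -0.20 and -0.22 (4 of 4 also adjusted over the list alone; adjusted p = 0.000178, and adjusted p = 0.0823 with an estimated correlation). Dot1l was at 83 ± 0.588 against 77.3 ± 0.315 CPM (adjusted p = 0.0636). The epithelial list rose in 16 of 24 genes (17 adjusted over the list alone; adjusted p = 5.3e-15). Hox, Meis and Pbx genes fell in 18 of 38 (20 adjusted over the list alone; adjusted p = 2.19e-07). TGF-beta targets rose in 7 of 10 (7 adjusted over the list alone; adjusted p = 4.1e-07). The p53 targets fell in 9 of 13 and rose in 1 (9 and 1 adjusted over the list alone; adjusted p = 1.36e-05). Every sterol synthesis gene measured, 17 of 17, fell (17 adjusted over the list alone; adjusted p = 5.52e-13), Insig1 from 123 ± 1.88 to 94.5 ± 5.22 CPM and Lss by -0.32 ± 0.04. Inflammatory factors rose in 7 of 14 and fell in 2 (7 and 2 adjusted over the list alone; adjusted p = 0.00209), Ccl2 by 0.82 ± 0.05. Immediate early genes rose in 8 of 13 (8 adjusted over the list alone; adjusted p = 4.14e-07, and adjusted p = 0.0749 with an estimated correlation), Junb and Egr1 by 0.52 ± 0.04 and 0.44 ± 0.04. In the mid window libraries Lars2, a mitochondrial leucyl-tRNA synthetase gene, stood at 5820 and 13600 CPM, against between 82.6 and 166 CPM in the other 12 timecourse libraries, and the count was 3971 without Lars2 and Mtrnr2l. Whether these reads come from the gene or from ribosomal RNA was not tested. DESeq2 called 1269 genes higher and 1856 lower, and limma on TPM 1478 higher and 2171 lower.

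**Figure D2:**
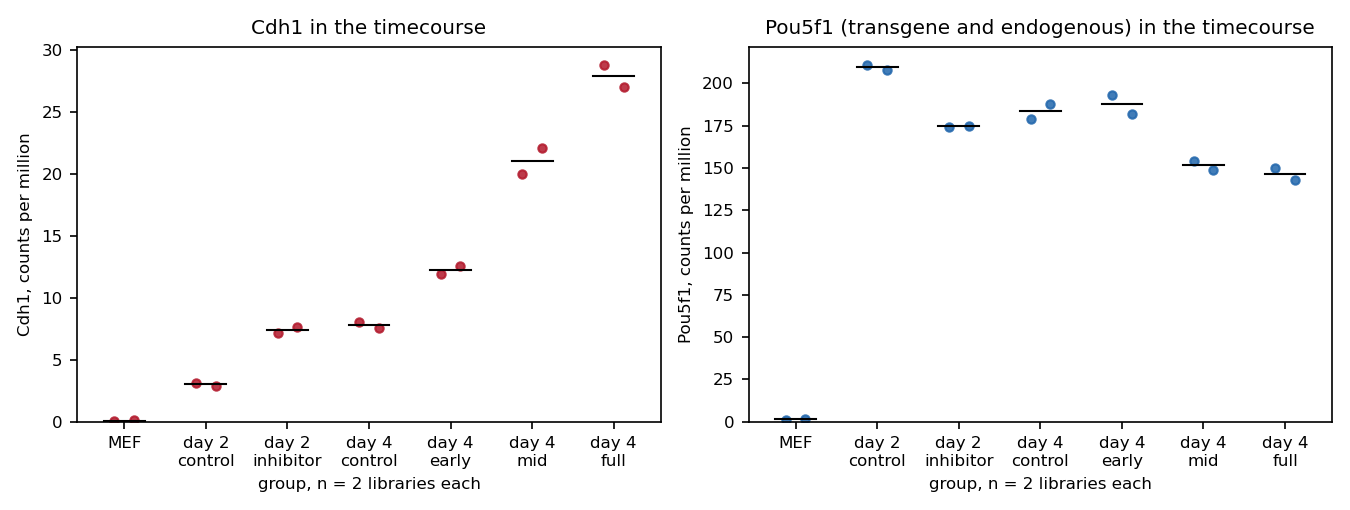
Cdh1 and Pou5f1 in the timecourse in CPM (vertical axes), with one point per library and a bar at the mean of the 2 libraries of each group (horizontal axis). Cdh1 was lowest in uninduced MEFs and highest after the full window of inhibitor, at a mean of 27.9 CPM.

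The early and mid windows were compared directly, and 3075 genes differed (1585 higher and 1490 lower after the early window; 8 and 181 of them by 2-fold or more). Cdh1 and Krt8 were lower after the early window by -0.79 ± 0.08 (adjusted p = 9e-10) and -1.08 ± 0.11 log2, as were Col28a1 (-1.14 ± 0.09), Pappa2 (-1.11 ± 0.09) and Ccl2 (-0.58 ± 0.05). Aldh3a1, at 355 ± 1.93 against 184 ± 0.358 CPM, the amino acid transporter gene Slc7a3 (0.99 ± 0.07), Avil (0.91 ± 0.08), Fgf4 (0.90 ± 0.09), Hoxa10 (0.48 ± 0.05) and Rrm1 (0.45 ± 0.03) were higher. Each reprogramming factor was higher after the early window (4 of 4 also adjusted over the list alone; adjusted p = 8.9e-08), Pou5f1 by 0.31 ± 0.04. Epithelial genes were lower in 12 of 24 (14 adjusted over the list alone; adjusted p = 3.78e-08) and inflammatory factors in 9 of 14 with 1 higher (11 and 1 adjusted over the list alone; adjusted p = 2.7e-06). Oxidative phosphorylation genes were lower in 6 of 18 (7 adjusted over the list alone; adjusted p = 0.0049, and adjusted p = 0.241 with an estimated correlation). Without early window replicate 2 or mid window replicate 2 the count was 1667 or 1762, and DESeq2 called 1394 genes higher and 840 lower.

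An interaction asked whether the full window equalled the early and mid effects added together; 1455 genes departed from the sum (847 higher, 608 lower). All 17 sterol synthesis genes lay above the sum (17 adjusted over the list alone; median 0.48 log2, camera adjusted p = 5.21e-56). Fdps was at 149 ± 0.271 CPM after the full window, 120 ± 0.964 after the mid, 119 ± 1.09 after the early window and 142 ± 2.43 in the control, an interaction of 0.56 ± 0.05 (adjusted p = 2.3e-11). The sterol genes Sc4mol and Cyp51 had interactions of 0.63 ± 0.06 and 0.50 ± 0.05. Inhba, an activin subunit gene, Itga3, Dsp and Krt19 also lay above the sum (0.82 ± 0.11, 0.79 ± 0.11, 0.64 ± 0.07 and 0.72 ± 0.08). Lying below it were Igfbp5 (-0.95 ± 0.07), the thyroid hormone-binding gene Crym (-0.90 ± 0.05), Dusp1 (-0.50 ± 0.09) and Junb (-0.30 ± 0.06). Cdh1 was not called (-0.24 ± 0.12, adjusted p = 0.191). Immediate early genes lay below the sum in 6 of 13 (6 adjusted over the list alone; adjusted p = 0.000385, and adjusted p = 0.351 with an estimated correlation). Above it lay 5 of 24 epithelial genes (5 adjusted over the list alone; adjusted p = 0.00585, and adjusted p = 0.102 with an estimated correlation). Lars2 was at -6.24 ± 0.58 here, and without it and Mtrnr2l the count was 1440. Without day 4 control replicate 1 or 2 or early window replicate 1 the count was 861, 792 or 860. The split was 697 higher to 312 lower with DESeq2 and 1163 to 240 with limma on TPM.

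**Figure D3:**
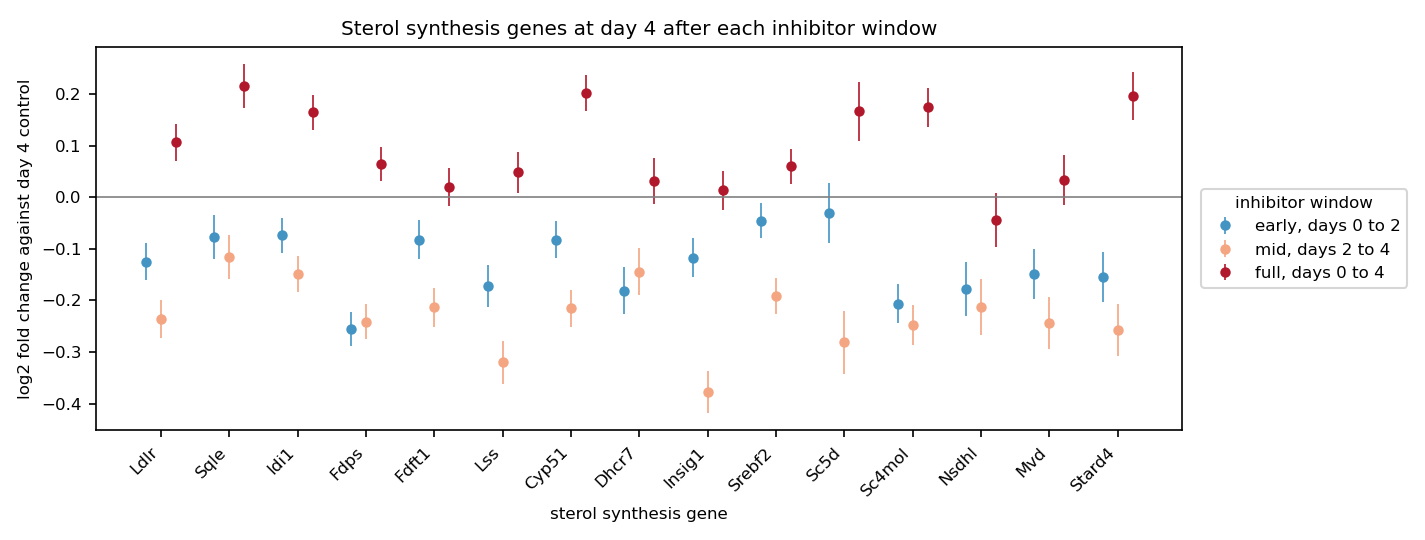
Log2 fold change against the day 4 control (vertical axis), with SE bars, of 15 of the 17 sterol synthesis genes (horizontal axis) after the early, mid and full inhibitor windows; n = 2 libraries per group. After the mid window all 15 lay below 0 and passed the test.

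The effect of the inhibitor at day 4 was set against that at day 2, and 1329 genes differed (812 higher, 517 lower). Dsp had a difference of 0.74 ± 0.07, Krt8 of 0.95 ± 0.18 and Cdh1 of 0.55 ± 0.14 (adjusted p = 0.00818). The Cdh1 call was lost without day 2 control replicate 1 or day 4 control replicate 2. Igfbp5 fell by day 4 and not at day 2, with a difference of -2.32 ± 0.09, and Abi3bp, Cdkn1c and Cxcl12 had differences of -1.87 ± 0.10, -1.18 ± 0.10 and -0.84 ± 0.05. Epithelial genes were higher in 10 of 24 (11 adjusted over the list alone; adjusted p = 2.46e-09) and contractile and YAP targets in 7 of 11 (9 adjusted over the list alone; adjusted p = 2.71e-11), Ctgf by 0.63 ± 0.04. Sterol synthesis genes were higher in 10 of 17 (14 adjusted over the list alone; adjusted p = 1.06e-10), Idi1 by 0.32 ± 0.05. So were glycolysis genes in 8 of 12 (9 adjusted over the list alone; adjusted p = 1.8e-06, and adjusted p = 0.0636 with an estimated correlation). Interferon genes were higher in 3 of 14 (4 adjusted over the list alone; adjusted p = 0.00108), Gbp2 by 1.49 ± 0.17. Hox genes were lower in 9 of 38 and higher in 1 (12 and 1 adjusted over the list alone; adjusted p = 3.9e-05), Hoxa11 by -0.73 ± 0.11. Of the 1264 genes raised at day 2, 926 were also raised by the full window at day 4, 697 by the mid window and 206 by the early window, after which the inhibitor had been absent for days 2 to 4. Of the 1319 lowered at day 2 the numbers were 844, 772 and 143. The median change of the genes raised at day 2 was 0.45 log2 then, and 0.50, 0.33 and 0.10 after the full, mid and early windows at day 4. Without day 4 control replicate 2 the count of 1329 was 880, and a fit of only these groups called 891 higher and 949 lower.

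The sort asked first how cells with and without surface CDH1 differed in the absence of inhibitor. Cdh1 was at 46.3 ± 0.45 CPM in the CDH1-positive and 7.25 ± 0.0197 CPM in the CDH1-negative fraction (2.67 ± 0.07 log2, adjusted p = 6.97e-63). Epithelial genes were higher in 25 of 30 (25 adjusted over the list alone; camera adjusted p = 4.04e-49), including Spint1 (1.49 ± 0.07) and the membrane protease gene St14 (1.56 ± 0.07). Krt8 was at 70.6 ± 2.18 against 30.8 ± 1.95 CPM and Sfn at 32.4 ± 1.66 against 11.3 ± 0.406 CPM. Macrophage and leukocyte genes were higher in 10 of 10 (10 adjusted over the list alone; adjusted p = 2.23e-64). The lysozyme gene Lyz2 was at 34 ± 1.66 against 4.26 ± 0.0417 CPM, and Mrc1, Emr1 and Csf1r differed by 5.00 ± 0.17, 4.43 ± 0.25 and 2.56 ± 0.13. Interferon response genes were higher in 13 of 14 (13 adjusted over the list alone; adjusted p = 1.39e-29), Isg15 at 68.1 ± 1.41 against 37.4 ± 0.714 CPM and Ifi44 by 1.03 ± 0.06. Pluripotency genes were higher in 13 of 24 (14 adjusted over the list alone; adjusted p = 5.66e-08), Tdgf1 by 2.66 ± 0.21 and Sall4 by 1.51 ± 0.15. All 16 S phase and all 17 G2 and M phase genes were lower (16 and 17 adjusted over the list alone; adjusted p = 3.08e-17 and 6.27e-15), Rrm2 by -0.38 ± 0.03 and Top2a by -0.26 ± 0.03. The retinoic acid-binding protein gene Crabp1 was lower by -1.76 ± 0.05, fibrillin gene Fbn2 by -0.86 ± 0.03, Pthlh by -0.81 ± 0.11 and Smpd3 by -0.78 ± 0.10. Oxidative phosphorylation genes were lower in 6 of 18 and inflammatory factors higher in 10 of 14 with 1 lower (9, 10 and 1 adjusted over the list alone; adjusted p = 0.00368 and 0.00236, and adjusted p = 0.0792 with an estimated correlation for each). In all 3717 of 13968 genes differed (1793 higher, 1924 lower); DESeq2 called 2091, and limma on TPM 1933 higher and 884 lower.

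In CDH1-negative cells the inhibitor raised Cdh1 from 7.25 ± 0.0197 to 20.9 ± 0.0668 CPM (1.53 ± 0.07 log2, adjusted p = 1.25e-35) and the imprinted gene Peg10 from 44.6 ± 2.6 to 85.4 ± 1.77 CPM. Ntn1 rose by 0.90 ± 0.05, Bdh1 by 0.87 ± 0.08 and the adhesion gene Nrcam by 0.78 ± 0.09. Contractile genes fell. Tagln went from 1890 ± 1.3 to 1320 ± 5.78 CPM, Acta2 from 3080 ± 29.9 to 2360 ± 78.4 CPM, and Cnn1 and Myl9 by -0.83 ± 0.03 and -0.55 ± 0.03; 9 of the 11 contractile and YAP genes fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 1.35e-40). Interferon response genes fell in 10 of 14 and rose in 1 (11 and 1 adjusted over the list alone; adjusted p = 6.25e-09), Isg15 by -0.85 ± 0.06 and Usp18 by -0.95 ± 0.10. Epithelial genes rose in 16 of 30 and fell in 1 (16 and 1 adjusted over the list alone; adjusted p = 4.65e-16), Cldn3 by 1.57 ± 0.17 and Krt8 by 0.49 ± 0.05. Further decreases were those of Myom1 (-1.13 ± 0.10), Nnat (-0.86 ± 0.09), Nptx2 (-0.81 ± 0.09) and Aspn (-0.79 ± 0.09). Factor genes were lower too: Pou5f1, Sox2, Klf4 and Myc fell by -0.24, -0.22, -0.17 and -0.13 (4 of 4 also adjusted over the list alone; adjusted p = 8.71e-05, and adjusted p = 0.156 with an estimated correlation). Dot1l was at 83.4 ± 0.314 with and 84.6 ± 3.86 CPM without inhibitor (adjusted p = 0.778). Mesenchymal regulators fell in 10 of 20 and rose in 2, and p53 targets fell in 11 of 13 and rose in 2 (11, 4, 11 and 2 adjusted over the list alone; adjusted p = 5.63e-05 and 0.00179). Epidermal genes rose in 6 of 11 and neural genes in 5 of 12 (7 and 6 adjusted over the list alone; adjusted p = 0.00239 and 0.000872). Each of these 4 calls had adjusted p = 0.156 with an estimated correlation. The integrin gene Itga5 changed by -0.41 ± 0.03. In all 2607 genes changed (1092 higher, 1515 lower); DESeq2 called 1335, and limma on TPM 1030 higher and 742 lower.

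In CDH1-positive cells, in which 2631 genes changed (1163 higher, 1468 lower), interferon response genes showed large decreases. Isg15 fell from 68.1 ± 1.41 to 26.9 ± 1.38 CPM (-1.34 ± 0.05 log2, adjusted p = 7.96e-47), Ifi44 by -1.18 ± 0.06, Oasl2 by -1.11 ± 0.09, Usp18 by -1.06 ± 0.08 and Xaf1 by -0.88 ± 0.05. In the list 11 of the 14 genes fell and 1 rose (13 and 1 adjusted over the list alone; adjusted p = 2.22e-41). Macrophage genes, abundant in this fraction, fell in 4 of 10 (7 adjusted over the list alone; adjusted p = 0.00109, and adjusted p = 0.11 with an estimated correlation), Lyz2 from 34 ± 1.66 to 21.9 ± 0.28 CPM. Cdh1 rose from 46.3 ± 0.45 to 69.9 ± 1.25 CPM (0.59 ± 0.04), Epcam by 0.72 ± 0.09, Cldn3 by 1.64 ± 0.16 and the desmosome gene Pkp1 by 0.80 ± 0.09. The epithelial list rose in 14 of 30 and fell in 1 (16 and 1 adjusted over the list alone; adjusted p = 4.47e-11, and adjusted p = 0.0535 with an estimated correlation). Peg10 (0.94 ± 0.04), Col15a1 (0.88 ± 0.05), the transglutaminase gene Tgm3 (0.88 ± 0.07), Ntn1 (0.86 ± 0.05), Bdh1 (0.84 ± 0.08) and Nanog (0.89 ± 0.15) rose as well. Contractile and YAP genes fell in 9 of 11 and rose in 1 (10 and 1 adjusted over the list alone; adjusted p = 8.15e-36), Cnn1 by -0.77 ± 0.03 and Tagln by -0.48 ± 0.02. The factors Pou5f1, Sox2, Klf4 and Myc fell by -0.20, -0.23, -0.14 and -0.11 (4 of 4 also adjusted over the list alone; adjusted p = 0.000352, and adjusted p = 0.17 with an estimated correlation). Hox genes fell in 10 of 38 (14 lower and 1 higher adjusted over the list alone; adjusted p = 0.00247, and adjusted p = 0.172 with an estimated correlation), Hoxc8 by -0.49 ± 0.06. Sterol synthesis genes fell in 10 of 17 (13 adjusted over the list alone; adjusted p = 2.74e-05, and adjusted p = 0.0535 with an estimated correlation), Idi1 by -0.21 ± 0.04. G2 and M phase genes rose in 8 of 17 (10 adjusted over the list alone; adjusted p = 0.000352, and adjusted p = 0.143 with an estimated correlation). Dot1l was at 79.7 ± 2.39 with and 75.2 ± 1.18 CPM without inhibitor (adjusted p = 0.104). The count of 2631 was 1674 without CDH1-positive control replicate 1 and 1372 with DESeq2, and limma on TPM called 979 higher and 805 lower.

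The effects in the sorted fractions were then tested against each other, and 26 genes differed (7 higher, 19 lower in the CDH1-positive fraction). Cdh1 responded less in CDH1-positive cells, by -0.93 ± 0.09 log2 (adjusted p = 1.44e-14), and the interferon genes Bst2 (-0.68 ± 0.06), Ifi44 (-0.62 ± 0.09) and Isg15 (-0.48 ± 0.07) fell further there. Bst2 went from 87.9 ± 0.22 to 56.2 ± 0.904 CPM in CDH1-positive cells and was at 52.6 ± 2.01 and 53.8 ± 0.713 CPM without and with inhibitor in CDH1-negative ones. The interferon list was lower in 4 of 14 genes (7 adjusted over the list alone; adjusted p = 6.69e-22). Sterol synthesis genes had a median difference of -0.12 with none of 17 called over all genes and 3 lower adjusted over the list alone (adjusted p = 6.03e-11). The chemokine genes Ccl2 and Ccl7 differed by -0.32 ± 0.05 and -0.34 ± 0.05, and Crabp1 by 0.50 ± 0.07. Across genes, which are not independent replicates, the log2 changes in the 2 fractions had Pearson r = 0.49, and 95.3% of the 3637 genes called in either had the same sign in both. DESeq2 called 11 and limma on TPM 9 of these differences.

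**Figure D4:**
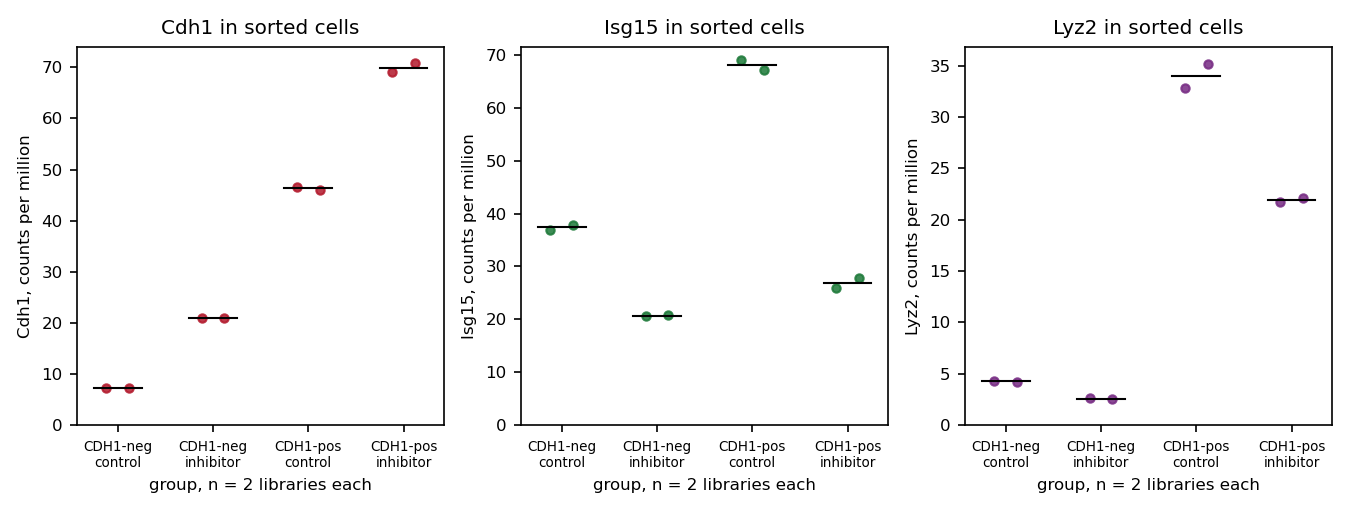
Cdh1, Isg15 and Lyz2 in the sorted cells in CPM (vertical axes), one point per library and a bar at the mean of the 2 libraries in each of the 4 groups (horizontal axis). Isg15 and Lyz2 were both higher in the CDH1-positive control cells, at means of 68.1 and 34 CPM.

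The lentivirus experiment first compared the 2 viruses in MEFs, where Cdh1 was not separated from virus dose. Cdh1 stood at 171 and 179 CPM in the Cdh1 virus MEF libraries and at 0.412 and 0.486 CPM with the empty virus, and in day 2 cells at 121 ± 3.09 against 5.2 ± 0.337 CPM. Interferon response genes were higher with the Cdh1 virus in MEFs in 13 of 14 (14 adjusted over the list alone; camera adjusted p = 6.69e-105). Isg15 was at 65.2 ± 0.0751 against 20.6 ± 0.301 CPM (1.66 ± 0.09 log2, adjusted p = 3.27e-12). Ifit1 and Ifit3, whose near-identical relatives make their counts uncertain, differed by 1.85 ± 0.09 and 1.44 ± 0.09. Macrophage and leukocyte genes were lower in 9 of 11 (10 adjusted over the list alone; adjusted p = 1.22e-36). Lyz2 was at 673 ± 77 against 1130 ± 80.5 CPM, Emr1 at -0.90 ± 0.09, and outside the list Tlr7, Msr1 and C1qa changed by -1.11, -1.08 and -0.99. Contractile and YAP genes were higher in 4 of 11 (6 adjusted over the list alone; adjusted p = 2.58e-09), Ctgf by 0.42 ± 0.06. The epithelial list was higher in 3 of 31, 1 of them Cdh1 (3 adjusted over the list alone; adjusted p = 2.61e-07, and adjusted p = 0.0769 with an estimated correlation). In all 171 of 15044 genes changed (92 higher, 79 lower). The count was 13 without the macrophage list and the genes higher in CDH1-positive cells, a choice made after seeing the data. On TPM values limma called 77 higher and 102 lower.

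At day 2 without inhibitor, the Cdh1 virus left 135 genes different from the empty virus, 22 higher and 113 lower. Macrophage genes were lower in 9 of 11 (10 adjusted over the list alone; adjusted p = 5.42e-59). Lyz2 was at 57.6 ± 1.02 against 169 ± 7.53 CPM (-1.55 ± 0.08 log2, adjusted p = 2.34e-11), Emr1 at -1.41 ± 0.10 and the complement genes C1qa and C1qc at -1.28 ± 0.13 and -1.27 ± 0.11. Pluripotency genes were lower in 10 of 30 (15 adjusted over the list alone; adjusted p = 7.7e-21), all at low levels. ESC RNA or reads in the empty virus libraries could give this call, so no effect of Cdh1 is drawn from it. Dppa5a was at 0.0155 ± 0.0219 against 1.91 ± 0.41 CPM, and Lin28a at 0 in both Cdh1 virus libraries and 0.9 ± 0.254 CPM with the empty virus (its call was lost without empty virus replicate 1). The median level of 36 ESC-specific genes was 0.229% of that in ESCs in the empty virus controls and 0.0205% with the Cdh1 virus. Igfbp5 rose by 0.55 ± 0.08. Isg15 was not higher, at 2.08 and 2.17 against 2.92 and 3.17 CPM. S phase and G2 and M phase lists were called lower with no gene of either called over all genes (5 and 0 lower adjusted over the list alone; adjusted p = 7.23e-06 and 2.21e-05). Contractile genes were higher in 2 of 11 (3 adjusted over the list alone; adjusted p = 7.23e-06) and amino acid stress genes in 1 of 14 (7 adjusted over the list alone; adjusted p = 8.31e-05). The count was 79 on TPM values, 111 without the genes at least 16-fold higher in ESCs, and 13 without the macrophage list and the genes higher in CDH1-positive cells. A fit of only these groups called 208, 55 higher and 153 lower.

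The inhibitor was tested at day 2 again in cells with the empty virus, and 1013 of 15044 genes changed (484 higher, 529 lower). Cdh1 was at 5.2 ± 0.337 CPM without and 4.57 ± 1.86 CPM with inhibitor (-0.14 ± 0.17 log2, adjusted p = 0.701). In these libraries ESC-specific genes stood at 0.203% and 0.134% of their ESC level without and 0.162% and 0.301% with inhibitor, and that share of the Cdh1 level in ESCs is 1.5, 0.99, 1.19 and 2.22 CPM. The log2 change of Cdh1 was 0.18 without inhibitor replicate 1, and -0.68 and called without inhibitor replicate 2. The epithelial list was not called, with 1 of 31 genes higher (0 adjusted over the list alone; adjusted p = 0.781). Among the genes that rose were the cytokine genes Tnfsf18, Ccl20 and Tnfsf15 by 1.06 ± 0.12, 0.98 ± 0.11 and 0.85 ± 0.08, Rgs4 by 0.98 ± 0.12, and Fgf10 by 0.85 ± 0.10. Ptgs2 rose from 76.4 ± 0.42 to 129 ± 9.03 CPM and Lox from 2210 ± 66.4 to 3340 ± 86.7 CPM. Avil, an actin-binding protein gene, fell from 39.7 ± 1.31 to 13.9 ± 1.28 CPM, Actg2 from 280 ± 9.35 to 156 ± 1.08 CPM, Nnat from 20.1 ± 0.554 to 11 ± 0.269 CPM, Vtcn1 by -0.90 ± 0.15 and the integrin gene Itgb4 by -0.77 ± 0.10. Pou5f1, Sox2, Klf4 and Myc fell by -0.41, -0.53, -0.26 and -0.25 (4 of 4 also adjusted over the list alone; adjusted p = 3.16e-06). Sox2 and Klf4 were not called without empty virus control replicate 1 or inhibitor replicate 1, and Myc was not without any of the 4 libraries. Dot1l was at 43.4 ± 0.717 without and 40.1 ± 2.18 CPM with inhibitor (adjusted p = 0.399).

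In the same comparison inflammatory factors rose in 6 of 14 (8 adjusted over the list alone; adjusted p = 4.59e-10). Sterol synthesis genes fell in 8 of 17 (12 adjusted over the list alone; adjusted p = 6.4e-12), Fdps by -0.41 ± 0.06. S phase and G2 and M phase genes fell in 6 of 16 and 4 of 17 (9 and 6 adjusted over the list alone; adjusted p = 0.00011 and 0.000642), Mcm7 by -0.41 ± 0.07. Glycolysis genes fell in 4 of 12 and immediate early genes rose in 4 of 13 and fell in 1 (6, 6 and 1 adjusted over the list alone; adjusted p = 0.000251 and 0.0063, and adjusted p = 0.222 and 0.377 with an estimated correlation). Ctgf, Cxcl12 and Ccl2 rose by 0.65 ± 0.06, 0.53 ± 0.06 and 0.43 ± 0.07. The count of 1013 was 296 and 428 without empty virus control replicate 1 or 2 and 270 without inhibitor replicate 1, and limma on TPM called 768 genes higher and 247 lower.

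With the Cdh1 virus, the inhibitor changed 759 genes at day 2 (424 higher, 335 lower). Cdh1 was at 113 ± 0.00879 with and 121 ± 3.09 CPM without inhibitor (-0.10 ± 0.09, adjusted p = 0.566). Tnfsf15 rose from 17 ± 0.415 to 32.9 ± 0.815 CPM (0.95 ± 0.08, adjusted p = 1.27e-07), Ccl20 by 0.99 ± 0.11, Il6 by 1.02 ± 0.17, Fgf10 by 0.84 ± 0.09, and Gabra3 by 0.82 ± 0.10. Also higher were Tnfsf18 by 0.81 ± 0.12, Gdf6 by 0.79 ± 0.10 and Lox by 0.46 ± 0.07. Actg2 fell from 307 ± 5.67 to 154 ± 4.25 CPM, Avil by -1.17 ± 0.10, Nnat by -0.85 ± 0.09, Itgb4 by -0.77 ± 0.10, Mpeg1 by -0.60 ± 0.09 and Chchd10 by -0.58 ± 0.10. Sterol synthesis genes fell in 9 of 17 (16 adjusted over the list alone; adjusted p = 4.37e-17), Fdps by -0.45 ± 0.06 and Fdft1 by -0.38 ± 0.06. Inflammatory factors rose in 8 of 14 (9 adjusted over the list alone; adjusted p = 3.78e-09), and amino acid stress genes fell in 3 of 14 (6 adjusted over the list alone; adjusted p = 0.00102). Pou5f1 fell by -0.39 ± 0.06 and Klf4 by -0.25 ± 0.05, while Sox2 was not called (-0.24 ± 0.11, adjusted p = 0.227). The factor list was lower in 3 of 4 (4 adjusted over the list alone; adjusted p = 2.79e-05). Klf4 was not called without Cdh1 virus control replicate 2. TGF-beta targets rose in 4 of 10 (4 adjusted over the list alone, with 1 lower; adjusted p = 0.00619, and adjusted p = 0.0879 with an estimated correlation). Dot1l was at 41.6 ± 0.413 without and 39.3 ± 0.993 CPM with inhibitor (adjusted p = 0.56). The count of 759 was 255 and 124 without Cdh1 virus control replicate 1 or 2, 1253 and 307 without inhibitor replicate 1 or 2, 138 when only these groups were fitted and 267 on TPM values.

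Whether the inhibitor acted differently with the Cdh1 virus was tested directly. With edgeR 0 genes passed (smallest adjusted p = 0.228), 1126 had an unadjusted p under 0.05, DESeq2 called 26 of the 1607 genes left by its own filtering, limma on TPM 0 and edgeR without the low-count filter 5. Cdh1 had a difference of 0.04 ± 0.19. Leaving out empty virus inhibitor replicate 1 or 2 or Cdh1 virus control replicate 1 gave 1 gene each, and leaving out Cdh1 virus control replicate 2 or Cdh1 virus inhibitor replicate 2 gave 2. The contractile list was called lower with a median of -0.07 and no gene called (3 lower adjusted over the list alone; adjusted p = 0.00541, and adjusted p = 0.13 with an estimated correlation). The macrophage list was called higher (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.012, and adjusted p = 0.272 with an estimated correlation).

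Day 2 inhibitor effects from the timecourse and from the empty virus cells rest on separate libraries and were compared across 14159 genes, which are not independent replicates. Their log2 changes had Pearson r = 0.15 (Spearman rho = 0.28), and r = 0.35 among 9724 genes with a mean log2 CPM of at least 3. Of the 3136 genes called in either, 74.4% had the same sign. Of all genes 136 were higher and 257 lower in both, where independent lists would share 41.8 and 49. Nnat fell and Ccl2 and Lox rose in both. A joint fit of the 2 experiments tested the difference of the effects and called 524 genes, with Cdh1 further up in the timecourse by 1.42 ± 0.21 log2 (adjusted p = 7.89e-05). Depth and virus differed between the 2 experiments, of which only the timecourse was described as paired-end and spiked. Cells differed too: Myc in uninduced MEFs stood at 110 and 108 CPM in the timecourse and 19.7 and 20.9 CPM with the empty virus. Y-linked Eif2s3y lay at 8.51% of its ESC level in the timecourse day 2 controls and 0.0559% in the empty virus controls. Sex composition may thus differ. These differences could not be separated, and the empty virus libraries held the ESC transcripts given above. The timecourse day 2 effect and that in CDH1-negative cells, also on separate libraries, had r = 0.45 across 13798 genes, and 85.1% of the 3851 genes called in either had the same sign.

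ESCs were compared with empty virus MEFs, and 13338 of 15044 genes differed (6698 higher, 6640 lower), or 4901 higher and 7544 lower with limma on TPM. Dppa5a was at 1350 ± 145 CPM in ESCs and 0.045 ± 0.00114 CPM in MEFs, Pou5f1 at 1110 ± 40.7 and 1.03 ± 0.0373, Cdh1 at 737 ± 47.9 and 0.449 ± 0.0522. Dot1l was at 100 ± 7.9 and 37.9 ± 0.36 CPM (1.40 ± 0.07 log2, adjusted p = 1.71e-15). Dcn, Lum, Postn and Agtr2 were lower in ESCs by -9.63 ± 0.10, -9.58 ± 0.12, -10.07 ± 0.11 and -9.53 ± 0.12. Pluripotency genes were higher in 29 of 30, epithelial genes in 28 of 31 and germ cell genes in 10 of 10 (29, 28 and 10 adjusted over the list alone; adjusted p = 1.75e-15, 3.73e-09 and 0.000434). All 24 fibroblast and all 20 mesenchymal genes were lower (24 and 20 adjusted over the list alone; adjusted p = 3.27e-17 and 1.44e-11). Hox, Meis and Pbx genes were lower in 38 of 39 and oxidative phosphorylation genes higher in 17 of 18 (38 and 17 adjusted over the list alone; adjusted p = 1.27e-09 and 0.00521, the latter adjusted p = 0.14 with an estimated correlation).

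From this comparison 2383 genes at least 4-fold higher in ESCs and 2758 in MEFs formed sets chosen on the series' own libraries, which are no independent evidence of direction. Of these, 1795 and 2632 were tested in the timecourse and 1678 and 2525 in the sort. The ESC-high set was higher with the inhibitor in the full window (528 genes higher, 249 lower; adjusted p = 0.0161), after the early window (117 and 13; adjusted p = 0.000105), in CDH1-negative cells (247 and 80; adjusted p = 1.71e-05) and in CDH1-positive cells (291 and 79; adjusted p = 8.25e-06). The MEF-high set was higher at day 2 in the timecourse (472 and 268; adjusted p = 0.00223), with the empty virus (233 and 122; adjusted p = 0.0136) and with the Cdh1 virus (229 and 70; adjusted p = 0.000278). With the Cdh1 virus the ESC-high set was called lower with a median of -0.02 and a mean of 0.03 (10 higher, 59 lower; adjusted p = 0.0494). That call was lost with replicate number as a factor (adjusted p = 0.0707) and with 16-fold sets (adjusted p = 0.721). At day 2 in the timecourse and in the mid window the 4-fold ESC-high set was not called (adjusted p = 0.203 and 0.0521), but the 16-fold set was higher (95 and 28, and 140 and 33; adjusted p = 9e-05 and 3.43e-05). In the mid window the 16-fold MEF-high set was higher too (244 and 141; adjusted p = 0.0485). Endothelial and primitive endoderm genes were called in none of the 19 comparisons (smallest adjusted p = 0.138 with the inhibitor and 0.0763 in control cells, both at day 2; 2 and 1 of 7 and 6 higher, 0 and 4 lower).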

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

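The joint test of the day 2 effects in the timecourse and lentivirus experiments, and the tests on macrophage and interferon genes in the last paragraph, were chosen only after the result was seen. Each value in the next 3 paragraphs stands here because a test of the difference between 2 effects of the inhibitor passed its threshold, for single genes with edgeR and for lists with camera at both the preset and the estimated correlation.

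In the windows, the effect of days 0 to 2 differed according to whether the inhibitor stayed on for days 2 to 4, for 1455 genes. The sterol synthesis list had a median difference of 0.48 log2, with Fdps at 0.56, Sc4mol at 0.63 and Cyp51 at 0.50. Inhba, Itga3, Dsp and Krt19 stood at 0.82, 0.79, 0.64 and 0.72, and Igfbp5, Crym, Dusp1 and Junb at -0.95, -0.90, -0.50 and -0.30. Lars2, at -6.24, stood apart in both mid window libraries, and the source of its reads was not tested.

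Between day 4 and day 2 the effect differed for 1329 genes. Lists called had median differences of 0.80 (epithelial), 0.14 (mesenchymal regulators), 0.30 (contractile and YAP targets), -0.23 (Hox, Meis and Pbx) and -0.05 (p53 targets and cell cycle inhibitors). Further lists called were TGF-beta targets at 0.15, interferon response at 0.35, inflammatory and secreted factors at -0.04 and sterol synthesis at 0.22. Larger at day 4 were the effects on Gbp2 (1.49), Krt8 (0.95), Dsp (0.74), Ctgf (0.63), Cdh1 (0.55), Idi1 (0.32), Cyr61 (0.32) and Dot1l (0.22). Lower were those on Igfbp5 (-2.32), Abi3bp (-1.87), Cdkn1c (-1.18), Cxcl12 (-0.84) and Hoxa11 (-0.73).

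Between the sorted fractions the effect differed for 26 genes, and the lists called included interferon response at a median of -0.28 and sterol synthesis at -0.12. Single differences were Cdh1 -0.93, Bst2 -0.68, Ifi44 -0.62, Egr2 -0.54, Isg15 -0.48, Ccl7 -0.34, Ccl2 -0.32, Krt8 -0.27 and Crabp1 0.50. Between the timecourse and the empty virus cells at day 2, the effect differed for 524 genes, with Cdh1 at 1.42.

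Macrophage markers were higher in CDH1-positive cells and lower with the Cdh1 virus, and interferon genes fell further with the inhibitor in CDH1-positive cells. A candidate explanation for the first is a differing share of macrophages: of 67 genes outside the list that were lower with the Cdh1 virus in MEFs, 62 (92.5%) were called higher in CDH1-positive cells, against 12.8% of all genes tested there. Yet 67 of 92 genes higher with that virus were higher in CDH1-positive cells too, where the most abundant of the 10 list genes measured, Lyz2, Mrc1 and Csf1r, stood at 34, 13 and 11.5 CPM, and a sort against CD45 would remove such cells. A like fall of all macrophage transcripts does not alone account for the fall of the interferon genes. Of the 14, 4 fell further than Lyz2 (-0.63), the macrophage gene with the largest fall, by more than 2 combined SE (medians -0.64 and -0.36). The comparison cannot exclude a loss of macrophages that lowered interferon genes in other cells, or a loss of only some macrophages. Interferon genes also fell in CDH1-negative cells (median -0.32, Isg15 from 37.4 to 20.7 CPM), where Mrc1 and Emr1 stood at 0.404 and 0.245 CPM. Lyz2 was lower there too, at 2.59 and 2.56 CPM with inhibitor against 4.29 and 4.23 CPM without. The macrophage genes had a median of -0.20 in that fraction, and 1 of them was called lower. In which cells the interferon response fell was not tested.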

How the results depend on the processing

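The settings without the mid window libraries, without Lars2 and Mtrnr2l, without macrophage-related genes or without ESC genes, and those of the joint day 2 test, were chosen only after the result was seen. For named genes, 393 values were recomputed under alternatives, which gave 4412 values: 4309 kept direction and side of the threshold, 91 lost the call, 3 gained one and 9 changed sign. Those 9 were all of values not called: on TPM Myc after the early window (-0.012) and Dot1l in CDH1-negative cells (0.009), and the rest without 1 library. They were Dot1l at day 2 (-0.003 without control replicate 1, range to 0.071), Pou5f1 after the early window (-0.001 without day 4 control replicate 1 and -0.009 without early window replicate 1, range to 0.075) and Dot1l in CDH1-negative cells (0.026 without control replicate 2, range from -0.058). The others were Cdh1 with the empty virus (0.179 without inhibitor replicate 1, range from -0.683) and the difference of the Cdh1 effects between viruses. That was -0.036 without empty virus control replicate 2 and -0.285 without empty virus inhibitor replicate 1, with a range to 0.577. The cause of these changes was not tested.

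Counts moved by over 1.5 times in the following cases, and the cause was not tested except where fewer libraries or a stricter definition give it. With limma on TPM, 1706 genes changed at day 2, 490 after the early window, 79 with the Cdh1 virus at day 2, 267 with the inhibitor in Cdh1 virus cells, and 9 differed between fractions. DESeq2 called 1335 in CDH1-negative and 1372 in CDH1-positive cells, 2091 between control fractions, 11 for the difference between fractions and 26 for that between viruses, of only 1607 genes left by its filtering. A fit of only the compared groups called 1544 after the early window, 208 with the Cdh1 virus at day 2 and 138 with the inhibitor in Cdh1 virus cells, and no low-count filter gave 5 for the difference between viruses. Leaving out the macrophage list and genes higher in CDH1-positive cells left 13 genes with the Cdh1 virus in MEFs and 13 at day 2, by construction. A 2-fold minimum, stricter by construction, left 223 at day 2, 792 for the full, 25 for the early and 344 for the mid window, 189 between windows, 55 for their interaction and 140 for day 4 against day 2. It left 3087 and 4391 in control cells at days 2 and 4, 143 in CDH1-negative and 145 in CDH1-positive cells, 280 between fractions and 3 for their difference. It left 34 and 58 with the Cdh1 virus in MEFs and at day 2, and 32 and 19 for the inhibitor with empty and Cdh1 virus.

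Leaving out 1 library, where the lone library of a group was assumed to vary like the others, gave ranges that moved by over 1.5 times for 11 of the 19 comparisons. They were 1510 to 1583 at day 2, 380 to 450 after the early window, 1667 to 2385 between windows, 792 to 1224 for their interaction, 880 to 1135 for day 4 against day 2 and 1674 to 1883 in CDH1-positive cells. In the lentivirus experiment they were 87 to 133 and 63 to 74 with the Cdh1 virus in MEFs and at day 2, 270 to 896 and 124 to 1253 for the inhibitor with empty and Cdh1 virus, and 0 to 2 for the difference between viruses. The other 8 stayed within 1.5 times. Of 532 list tests 207 were called, and 107 with an estimated correlation. Of 28 tests of ESC and MEF sets 10 were called, 20 with an estimated correlation and 22 with fry, in which the same 10 were included. The agreement of the day 2 effects was r = 0.35 among genes with mean log2 CPM of at least 3, against 0.15.

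The direction with more genes turned often, and the cause was not tested. It turned in 10 comparisons on TPM, 6 without the low-count filter, 4 each with RLE and DESeq2, 3 with only the compared groups, 9 with a 2-fold minimum and 4 without 1 library. Without the filter, higher and lower genes were 1364 and 1229 at day 2, 2503 and 3005 in the full window, 1813 and 2459 in the mid window, 722 and 807 for day 4 against day 2, 5865 and 6185 in control cells at day 4, and 1829 and 1791 between control fractions. With RLE they were 1820 and 2257 in the mid window, 5868 and 6027 in control cells at day 4, 1884 and 1764 between fractions and 526 and 508 with the empty virus, and DESeq2 turned the same 4. On TPM they were 242 and 248 after the early window and 126 and 141 with the inhibitor in Cdh1 virus cells.

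RLE scaling moved the median of all genes by at most 0.069 log2. With replicate number as an added factor, 2561 genes changed at day 2, 172 with the Cdh1 virus in MEFs and 661 with the inhibitor in Cdh1 virus cells. The deviations of libraries with the same number in different groups correlated at between -0.09 and 0.11, so the numbers were not taken as pairs. Planned scaling to human spiked RNA was not run for 13 results, since the files hold no human genes. Small changes were recovered least on simulated data for the lentivirus experiment, with lower depth and a larger spread between replicates, and these were not separated.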

Other observations

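The tests on imprinted genes, on ESC transcripts and on library scaling were chosen only after the result was seen. Imprinted genes, expressed from 1 parental copy, were among those that the inhibitor changed in several experiments, and those given here were chosen after their values were seen. Peg10 rose in all 8 comparisons of inhibitor with control, by between 0.35 ± 0.08 with the Cdh1 virus and 1.37 ± 0.05 log2 in the full window. Nnat fell in 7 of them, by between -0.50 ± 0.06 in the mid window and -1.19 ± 0.07 at day 2, and was at -0.06 ± 0.06 after the early window. Igf2 fell by -0.40 ± 0.03 at day 2 and -1.16 ± 0.03 in the full window, and was not called in CDH1-positive cells (-0.06 ± 0.04). Cdkn1c rose at day 2 (0.54 ± 0.09) but fell in the full window at day 4 (-0.64 ± 0.04). A hypothesis is that imprinted genes respond more than other genes of their level. Without these 4 genes, the median absolute change of 15 listed genes in CDH1-negative cells was 0.189, above 99.6% of 10000 lists matched on level (median 0.0823), with 4 called higher and 3 lower. At day 4 the 18 genes tested lay at the percentile 83 (0.197 against 0.141, 4 higher and 5 lower), which leaves the hypothesis open there.

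The day 2 libraries with the empty virus held the traces of ESC transcripts given above, over 22 ESC-specific genes, chosen for levels of at most 0.05% in the Cdh1 virus controls. RNA or reads of ESCs are a candidate source. Control counts scattered around a single share of the ESC level with a chi-square per degree of freedom of 2.06 (1.06 with inhibitor). In the controls this exceeded counting noise, with the 22 genes between 0.0485% and 0.361%. Expression begun by the factors within 2 days is excluded as the whole source. The median share of 36 ESC-specific genes was 0.229% in these controls, 0.0581% in the timecourse day 2 controls and 0.0205% with the Cdh1 virus. The pooled share of the 22 genes, 0.169% and 0.0824% in the first 2, was 0.17% and 0.021% without Y-linked Eif2s3y. A sort of the day 2 cells before lysis would remove ESCs but neither stray RNA nor reads assigned to the wrong library, and these could not be separated here. Taking off the same share of its ESC level would leave Cdh1 at 3.46 and 4.45 CPM without and 2.06 and 3.67 CPM with inhibitor.

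Pou5f1, Sox2, Klf4 and Myc were lower with the inhibitor, by a median of -0.24 log2 at day 2. Scaling of the libraries as the cause stays open. The median change of all genes was -0.011 with RLE and -0.005 with TMM, but both methods set this median near 0 and no scaling to spiked RNA was made, so a fall of the factors per cell and a rise of other RNA cannot be told apart. Lower factor output may in turn have moved the genes that respond to the factors back toward MEFs, a test planned before the result: the inhibitor effect of the timecourse had a slope of -0.041 (-0.052 to -0.031 over 1000 resamplings of genes) on the response measured in the empty virus set over 9723 genes. The bound set beforehand was a slope of -0.05 or less, which lies within that range, so this and an effect apart from the factors cannot be told apart. The cassette and the endogenous genes were not separable in these counts.

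Lars2 stood at 1580 CPM in replicate 2 and 393 CPM in replicate 1 of the MEFs with the empty virus, and at 1830 and 387 CPM in replicates 1 and 2 of the empty virus cells with inhibitor. The other lentivirus libraries lay between 86.5 and 184 CPM, and the ESC libraries at 554 and 225 CPM. Mtrnr2l stood at 17.4 and 69 CPM in the mid window libraries, against between 5.24 and 16.3 CPM in the other timecourse libraries and between 26.8 and 78.5 CPM in the lentivirus libraries.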
